A study of Mus musculus with 12 samples.

How the data were processed

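The series holds ChIP-seq of mouse thymocytes, the developing T cells of the thymus, from 4 to 5 week old animals. Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 min, digested with 375 units of micrococcal nuclease for 0.5 h and then sonicated. Chromatin was precipitated with an antibody against the zinc-finger protein ZFAT, against histone H3 trimethylated at lysine 9 (H3K9me3, a mark of silenced chromatin), or against H3 acetylated at lysine 9 and lysine 27 (H3K9ac/K27ac, a mark of active promoters and enhancers). Of the 12 samples, 6 were ChIP libraries with peak lists and 6 were input or IgG control samples whose own reads were not analysed here. Each ChIP group had 1 library: ZFAT in floxed, Lck-Cre and B6 thymocytes, H3K9me3 in floxed thymocytes, and H3K9ac/K27ac in floxed and Lck-Cre thymocytes. Floxed mice carry a Zfat gene flanked by recombination sites, and Cre expressed from Lck is designed to remove the floxed sequence in T lineage cells. The B6 ZFAT library came with 1 list called against input and another called against IgG, so there were 7 lists.

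The lists are peaks in mm9 called by the authors with MACS, per the submitters' processing notes, which give no MACS version. The notes also name CASAVA 1.8.1, Trimmomatic 0.22 and SAMtools 0.1.18; the aligner is not given in the sources used here. Per the file headers, every list used an average fragment length of 150 bp, a p threshold of 1e-05, enrichment limits of 5 and 1000, a dynamic local background and 5000 bp of upstream padding. The headers of the floxed and Lck-Cre lists do not say which control library was used. Peaks were called per library, not on pooled libraries. Per the file headers, the P score and the Q score of each peak are −log10 values, of the caller's p and of its adjusted value, and the fold change is the authors' ratio of ChIP to local background. The lower enrichment limit did not act as a filter on the deposited fold, since 680 of the 1719 floxed ZFAT peaks lay under 5. P scores stop at 323.3, the ceiling of the caller; ties there were ordered by fold. The Q score exceeded the P score in 2245 floxed H3K9ac/K27ac peaks, which an adjustment for multiple testing cannot give, so it served only for 1 alternative. Scores and folds are the authors' values for each peak and were used to describe, rank or filter peaks within a list.

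Overlap was computed from the deposited coordinates, taken as 1-based and closed. A peak counted as overlapped when it shared at least 1 bp with a peak of the other list. Each percent has an exact Clopper-Pearson 95% interval, which covers counting error only. Chance was taken from 1000 circular shifts of one list within the span of each chromosome. A nearer form of chance moved the whole floxed ZFAT list by 5 to 50 kb in either direction. For the H3K9ac/K27ac peaks overlapped by ZFAT, the share also called in Lck-Cre was set beside 10000 random sets of floxed H3K9ac/K27ac peaks matched on the 10 deciles of P score. With 1 library per group, every comparison compares these libraries, not the conditions, and no p-value between conditions is given.

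The depth of the libraries is not stated in the lists and was inferred. The deposited fold and P score of a peak are together met by a whole number of fragments at the summit (the pileup) and a background, if the fold is (pileup + 1)/(background + 1) and p is the Poisson tail above the pileup. With a tolerance of 0.0001 on the P score, a whole pileup was found for 100% of the peaks below the ceiling in each list; 1 H3K9me3 peak had more than 1 solution. On simulated values drawn from the floxed ZFAT list, 981 of 981 pileups were recovered, and 3 of 981 folds built from fractional pileups were accepted by chance. The lowest background of a list, read as fragments spread evenly over the effective genome, implied about 1510000 ChIP fragments for floxed ZFAT, 1350000 for Lck-Cre ZFAT and 632000 for B6 ZFAT. It implied 2230000 for H3K9me3, 2190000 for floxed H3K9ac/K27ac and 1340000 for Lck-Cre H3K9ac/K27ac. Both B6 lists, which share a library, gave the same value. At the P ceiling only a lower bound of the pileup is known. Pileup intervals are exact Poisson 95% intervals for counting error only, and the thinning counts and simulated ranges also hold counting error only, except where fragments were drawn in groups. Pileups above 300, the most that distinct start positions could give, show that duplicate reads were not all removed. Background in this sense is the scaled control level at the peak, and 20 or more was called high. At the ceiling it is not known, and such peaks were not counted as high.

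The regions named in the report, other than the neighbouring ZFAT sites under other observations, followed a rule fixed before the data were examined, ranking by P score on the standard chromosomes. It took the 5 strongest floxed ZFAT peaks with a B6 peak called against input and no Lck-Cre peak, the 3 strongest with an Lck-Cre peak, and the 3 strongest Lck-Cre ZFAT peaks without a floxed one. It also took the 5 strongest H3K9me3 peaks, the 5 strongest floxed H3K9ac/K27ac peaks without an Lck-Cre one, the 3 strongest Lck-Cre H3K9ac/K27ac peaks without a floxed one, and the 3 strongest B6 peaks called against IgG.

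Alternatives were fixed beforehand for the overlap rule, the score threshold, the chromosomes, the list lengths, the choice of ZFAT peaks, the B6 control and the matching. Others were added after seeing the data. Gene positions in mm9 were not used here, and the lists pair no peak with a gene. The 2 results planned on promoters, with 10 gene lists, were therefore not made, and no gene is named beside a region. Matching on tag number was replaced by matching on the inferred pileup because the lists hold no tag column. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.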

Results

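ChIP-seq peak lists were compared for ZFAT, H3K9me3 and H3K9ac/K27ac in mouse thymocytes. ZFAT was profiled in floxed thymocytes, in thymocytes of the Lck-Cre line, in which Cre is designed to remove the floxed Zfat sequence in T lineage cells, and in B6 thymocytes; each was a single ChIP library without replicates. The lists held 1719 floxed, 108 Lck-Cre and 2000 B6 ZFAT peaks called against input, with 427 B6 peaks called against IgG. They held 2388 H3K9me3 peaks in floxed thymocytes, and 13016 floxed and 2225 Lck-Cre H3K9ac/K27ac peaks. All positions are in mm9. The fold and the P score (−log10 p) of a peak are those of the authors' caller, and the headers of the floxed and Lck-Cre lists do not name the control. Most ZFAT and H3K9me3 peaks were narrow, with median lengths of 172 bp for floxed ZFAT and 171 bp for H3K9me3, near the 150 bp fragment length. Floxed H3K9ac/K27ac peaks had a median length of 290 bp. The inferred pileup at the summit had a median of 9 fragments in floxed ZFAT peaks, 5 in Lck-Cre ZFAT peaks, 6 in B6 peaks called against input, 14 in H3K9me3 peaks, 38 in floxed H3K9ac/K27ac peaks and 18 in Lck-Cre H3K9ac/K27ac peaks. Most ZFAT peaks therefore rested on few fragments, with 971 of the 1719 floxed peaks at 10 or fewer. The B6 library was the shallowest, at about 632000 inferred fragments.

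The first comparison asked which ZFAT peaks were also called in the Lck-Cre line; the extent of the Zfat deletion was not measured in these lists. The floxed list held 1719 ZFAT peaks and the Lck-Cre list 108, a ratio of 15.9. Of the floxed peaks, 31 (1.803%, 95% interval 1.23% to 2.55%) were overlapped by an Lck-Cre peak, against a mean of 0.04 peaks over 1000 circular shifts. In the other direction, 35 of the 108 Lck-Cre peaks (32.4%, 23.7% to 42.1%) overlapped a floxed peak. The shared peaks were mostly the strongest of the floxed list. Of 51 floxed peaks with a P score of 50 or more, 30 (58.8%, 44.2% to 72.4%) were overlapped by an Lck-Cre peak, against 0 of 63 with a score from 20 to 50 (upper limit 5.69%) and 1 of the remaining 1605. Of the 23 floxed peaks at the ceiling of the P score, 22 were overlapped by an Lck-Cre peak. When both lists were taken at the length of the shorter, 27.8% of floxed peaks were overlapped.

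The strongest shared regions by the caller's score and fold were on chromosomes 17 and 7. At chromosome 17, 25252349 to 25253037, the floxed fold was 355 and the Lck-Cre fold 14.7, with an Lck-Cre pileup of 35 fragments and a floxed pileup of at least 397. At chromosome 7, 20147001 to 20147920, the folds were 312 in floxed and 14.4 in Lck-Cre thymocytes. At chromosome 7, 134919978 to 134921457, they were 311 and 79.2, and the P score was at the ceiling in both lists. The latter pair of regions also carried a floxed H3K9ac/K27ac peak, and none of these 3 regions carried an H3K9me3 peak or an Lck-Cre H3K9ac/K27ac peak. Of the 31 shared regions, 5 had a floxed control background of 20 or more. Among the other 26, of which 22 were at the P ceiling with an unknown background, the listed fold was lower in Lck-Cre than in floxed at all 26, with medians of 10.6 and 148. The inferred depths were close, at about 1510000 and 1350000 fragments. A fold also depends on the local background, which differed between the lists, in both directions, where it was known in both. The controls are not named either, so these folds describe each list and give no measured loss.

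**Figure D1:**
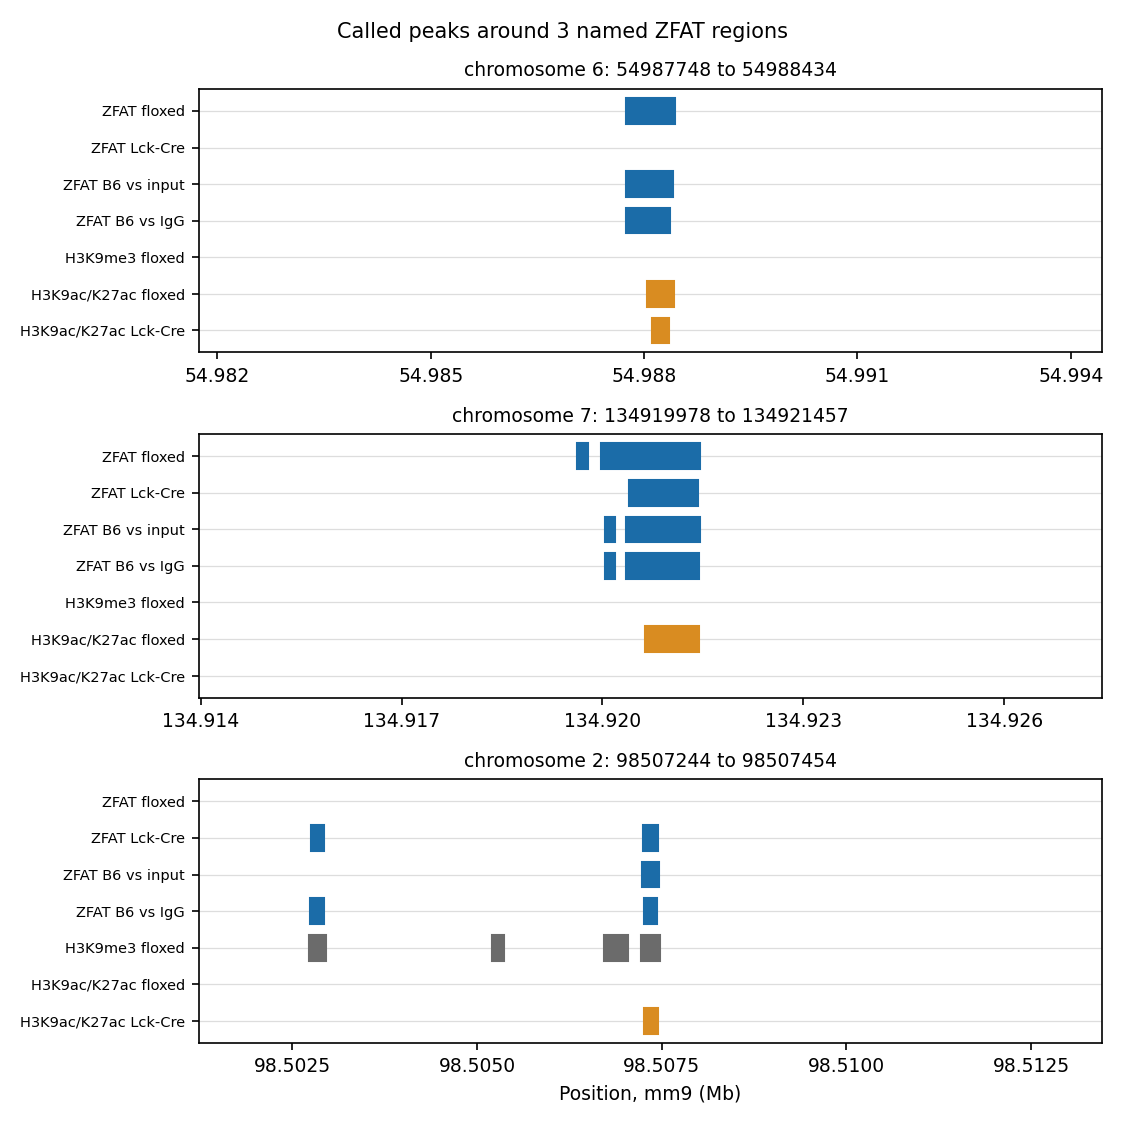
Called peaks of the 7 lists around 3 named ZFAT regions, each drawn to scale with 6 kb on either side (horizontal axis, mm9 position in Mb). Bars are peaks. The region on chromosome 6 has no Lck-Cre ZFAT peak, the one on chromosome 7 has ZFAT peaks in floxed, Lck-Cre and B6 thymocytes, and the one on chromosome 2 has 4 H3K9me3 peaks and no floxed ZFAT peak.

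The Lck-Cre list also held 73 peaks without a floxed counterpart. The 3 strongest lay at chromosome 2, 98507244 to 98507454 (fold 1.96, pileup 2768, Poisson 95% interval 2666 to 2873), at chromosome 2, 98502759 to 98502927 (fold 2.17, pileup 1077, interval 1014 to 1143), and at chromosome 9, 3023447 to 3023604 (fold 3.87, pileup 192, interval 166 to 221). Their control backgrounds were 1413, 495 and 48.9 scaled fragments, so at these regions the control was high as well. Both chromosome 2 regions also carried an H3K9me3 peak and a B6 ZFAT peak called against IgG.

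The second comparison set the floxed peaks beside those of B6 thymocytes, another line with an intact Zfat gene. Of 1719 floxed peaks, 142 (8.26%, 7.002% to 9.66%) were overlapped by a B6 peak called against input, against a mean of 0.583 and a highest value of 4 over the shifts. Conversely, 146 of the 2000 B6 peaks called against input (7.30%, 6.20% to 8.53%) overlapped a floxed peak. Recurrence of the floxed peaks followed the strength of the peak. Of the 51 floxed peaks with a P score of 50 or more, 50 (98.04%, 89.6% to 99.95%) had a B6 peak. This fell to 34 of 63 (54.0%, 40.9% to 66.6%) for scores from 20 to 50, 29 of 567 (5.11%, 3.45% to 7.26%) for scores from 10 to 20, and 29 of 1038 (2.79%, 1.88% to 3.99%) under 10. With B6 peaks called against IgG, 91 floxed peaks (5.29%, 4.28% to 6.46%) were overlapped, and 82 floxed peaks had a B6 peak in both B6 lists.

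The 5 strongest floxed peaks with a B6 peak and without an Lck-Cre peak were all present in both B6 lists. The first, at chromosome 8, 59029425 to 59029716, had a fold of 107 in floxed thymocytes and 54.9 in B6 against input, with no H3K9ac/K27ac peak in either list. At chromosome 6, 54987748 to 54988434, the floxed fold was 48.5 (pileup 186, interval 160 to 215) and the B6 fold 85.3. This region carried an H3K9ac/K27ac peak in floxed (fold 11.5) and in Lck-Cre thymocytes (fold 3.99). The peaks at chromosome 11, 76220676 to 76220999, chromosome 1, 133807105 to 133807803, and chromosome 7, 36340067 to 36340703, had floxed folds of 34.9, 25.003 and 33.5. Each of these overlapped a floxed H3K9ac/K27ac peak, with folds of 8.25, 17.4 and 9.58, and none overlapped an Lck-Cre H3K9ac/K27ac peak or an H3K9me3 peak.

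The B6 library was called against 2 controls. Of 427 peaks called against IgG, 290 (67.9%, 63.3% to 72.3%) overlapped a peak called against input, and 290 of the 2000 peaks called against input (14.5%, 13.0% to 16.1%) overlapped one called against IgG. Since the ChIP reads are the same, this comparison shows the effect of the control, not replication. The 3 strongest peaks against IgG were at chromosome 7, 134920349 to 134921446 (fold 436), chromosome 9, 99468649 to 99469455 (fold 368), and chromosome 7, 20147026 to 20147901 (fold 298). All of these had floxed and Lck-Cre ZFAT peaks and a floxed H3K9ac/K27ac peak.

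The series also set ZFAT beside histone marks. Of the floxed ZFAT peaks, 443 (25.8%, 23.7% to 27.9%) were overlapped by a floxed H3K9ac/K27ac peak, against a mean of 5.36 over circular shifts and 11.7 when the ZFAT list was moved by 5 to 50 kb. Among the 443, the ZFAT summit lay within the H3K9ac/K27ac peak in 434, at a median of 32 bp from the nearest acetylation summit. Being chosen by overlap favours such closeness, and no chance value is given for these distances. The share overlapped by acetylation was higher for the stronger peaks. It was 38 of 63 (60.3%, 47.2% to 72.4%) for scores from 20 to 50 and 30 of 51 (58.8%, 44.2% to 72.4%) at 50 or more. Under 10 it was 233 of 1038 (22.4%, 19.9% to 25.1%). Of the 113 floxed ZFAT peaks with a B6 peak and no Lck-Cre peak, 70 (61.9%, 52.3% to 70.9%) carried acetylation. Of the 82 floxed ZFAT peaks present in both B6 lists, with or without an Lck-Cre peak, 65 (79.3%, 68.9% to 87.4%) did. Among the 57 of these without an Lck-Cre peak it was 46 (80.7%, 68.1% to 90.0%). The 1577 floxed peaks without a B6 peak still overlapped acetylation in 354 cases (22.4%, 20.4% to 24.6%).

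**Figure D2:**
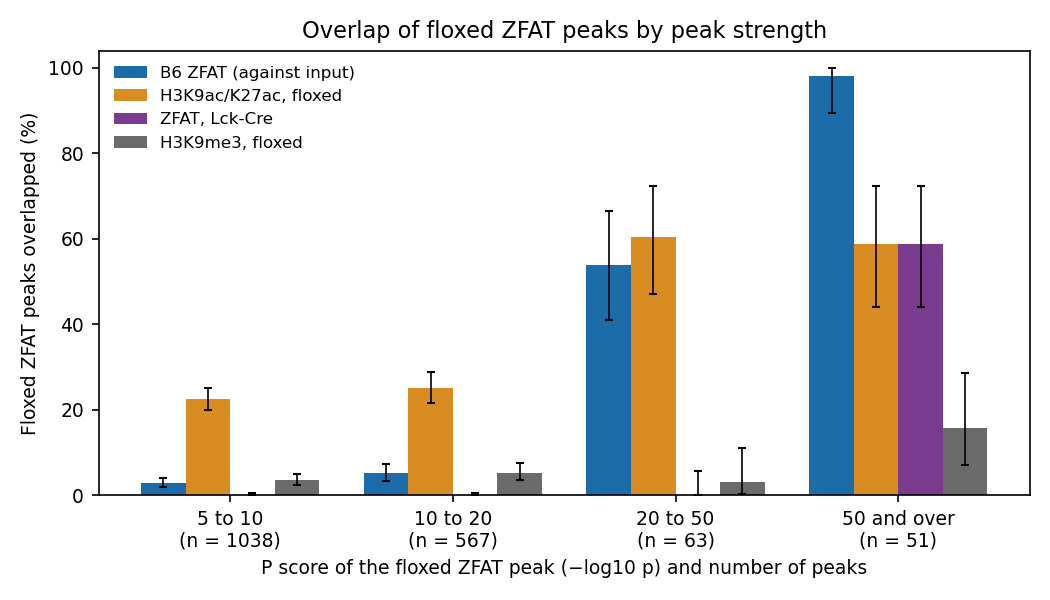
Percent of floxed ZFAT peaks (vertical axis) overlapped by peaks of 4 other lists, by band of P score (−log10 p, horizontal axis). Bars are observed percents and whiskers exact 95% intervals for counting error. B6 overlap runs from 2.79% under a score of 10 to 98.04% at 50 or more, and Lck-Cre overlap of more than 1 peak appears only in the highest band.

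H3K9me3 overlapped fewer ZFAT peaks, from a shorter list of 2388 peaks against 13016 for floxed H3K9ac/K27ac. Of the floxed ZFAT peaks, 77 (4.48%, 3.55% to 5.57%) were overlapped by an H3K9me3 peak, against a mean of 0.693 over the shifts and 1.0 when the list was moved. Relative to chance the order was the reverse. The H3K9me3 overlap was 111 times the shift mean, against 82.6 times for acetylation. With the list moved it was 77 times the mean, against 37.8 times. Only 2 of the 77 also carried H3K9ac/K27ac. Of the 142 floxed peaks with a B6 peak called against input, 11 (7.75%, 3.93% to 13.4%) overlapped H3K9me3. Of the 82 floxed peaks present in both B6 lists, 0 overlapped H3K9me3 (upper limit 4.40%). Of the 12 floxed peaks with a control background of 20 or more, 9 had a B6 peak called against input and 0 had one called against IgG. Of the 10 ZFAT peaks with a P score of 20 or more and an H3K9me3 peak, 9 lay where the control background was 20 or more. Over all 77, only 10 lay at such a background. Without regions of high control background, the share was 3.93% (67 of 1707). The strongest H3K9me3 peak, at chromosome 11, 3093063 to 3093602, had a fold of 5.29. It coincided with ZFAT peaks in floxed (fold 2.53, control background 146) and B6 thymocytes (fold 4.17 against input, control background 84.2). The next by score lay on chromosome 2 at 98507224 to 98507472, 98502721 to 98502961 and 98505205 to 98505359, with folds of 2.92, 2.47 and 2.76, and on chromosome 11 at 3035533 to 3035801 with a fold of 6.90. The last of these overlapped ZFAT peaks of the floxed list and the B6 list called against input, at control backgrounds of 74.1 and 22.4. The first chromosome 2 region carried ZFAT peaks of the Lck-Cre list and both B6 lists. The second carried those of the Lck-Cre list and the B6 list called against IgG, and the third carried no ZFAT peak.

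H3K9me3 and acetylation seldom met. Of 2388 H3K9me3 peaks, 105 (4.40%, 3.61% to 5.30%) were overlapped by a floxed H3K9ac/K27ac peak, above the mean of 7.25 and the highest value of 16 over the shifts. At P scores of 10 or more in both lists the share was 1.85% (22 of 1186). The H3K9me3 list held narrow peaks, with only 121 of 2388 longer than 350 bp.

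The last comparison asked how acetylation differed between the floxed and Lck-Cre libraries. The floxed list held 13016 H3K9ac/K27ac peaks with a median fold of 8.62 and the Lck-Cre list 2225 with a median fold of 4.86. The ratio of peak numbers was 5.85, and 11.1 at P scores of 10 or more. Of the Lck-Cre peaks, 1669 (75.01%, 73.2% to 76.8%) overlapped a floxed peak. With both lists at 2225 peaks, the share was 41.5%. Conversely, 1600 of the 13016 floxed peaks (12.3%, 11.7% to 12.9%) were overlapped by an Lck-Cre peak, from 1.92% (1.25% to 2.82%) in the lowest decile of P score to 45.5% (42.7% to 48.2%) in the highest. The inferred depths were about 2190000 and 1340000 fragments.

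**Figure D3:**
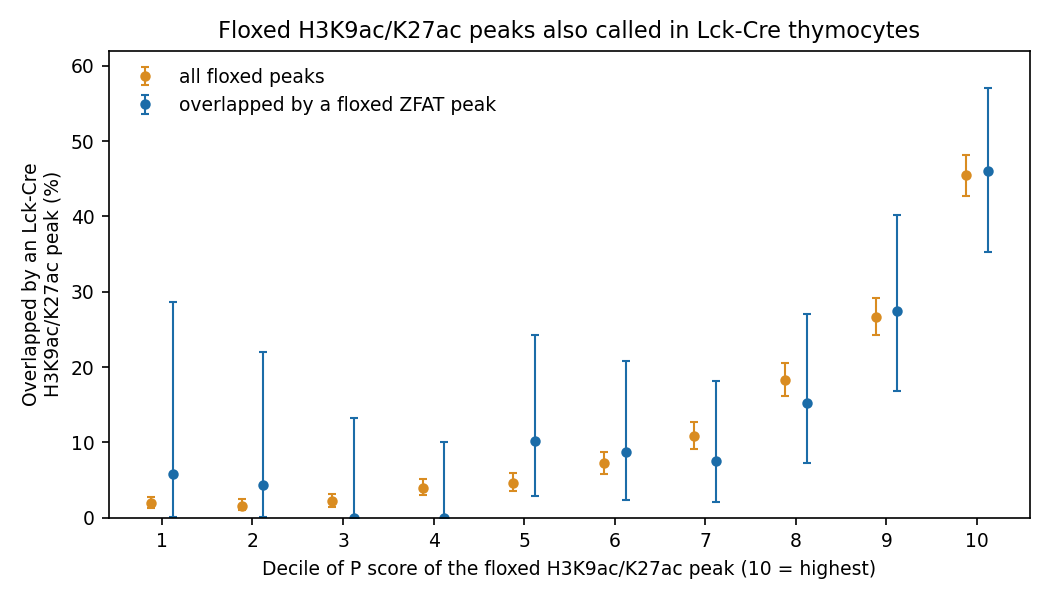
Percent of floxed H3K9ac/K27ac peaks overlapped by an Lck-Cre H3K9ac/K27ac peak (vertical axis) in each decile of the floxed P score (horizontal axis), for all floxed peaks and for those overlapped by a floxed ZFAT peak. Whiskers are exact 95% intervals for counting error. Over all peaks the percent reaches 45.5% in decile 10, and that of ZFAT-bound peaks reaches 46.0%.

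The strongest floxed acetylation peaks without an Lck-Cre peak were at chromosome 2, 31913825 to 31914120 (fold 80.4, pileup 96, interval 77.8 to 117), chromosome 1, 90173792 to 90174179 (fold 11.1, pileup 287, interval 255 to 322), and chromosome 11, 100980738 to 100981137 (fold 47.6, pileup 111, interval 91.3 to 134). They were followed by chromosome 11, 26493336 to 26493828 (fold 45.9), and chromosome 7, 4989827 to 4990118 (fold 55.5). Of these 5, the region on chromosome 1 carried a floxed ZFAT peak, with a fold of 2.52 at a control background of 20.4. The 556 Lck-Cre peaks without a floxed peak were small, with a median pileup of 4 fragments against 21 in the 1669 others. The strongest was the high-background region at chromosome 2, 98507255 to 98507448 (fold 1.54), followed by chromosome 17, 46811047 to 46811230 (fold 12.2, pileup 13, interval 6.92 to 22.2), and chromosome 10, 59747995 to 59748185 (fold 11.7, pileup 12, interval 6.20 to 20.96).

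ZFAT-bound acetylation peaks were compared with the rest to ask whether the peaks not called in Lck-Cre thymocytes concentrated at ZFAT sites. Of 447 floxed H3K9ac/K27ac peaks overlapped by a floxed ZFAT peak, 80 (17.9%, 14.5% to 21.8%) were also called in Lck-Cre, against 12.1% of the other 12569. ZFAT-bound acetylation peaks were stronger, with a median P score of 38.3 against 25.3. Random sets matched on score gave a mean of 17.997% with a 95% range of 15.0% to 21.3%, and the ZFAT-bound share lay at percentile 48.0 of these sets. The difference from the matched mean was -0.10 percentage points. For the 93 acetylation peaks at floxed ZFAT peaks that also had a B6 peak, 24 (25.8%) were called in Lck-Cre against a matched mean of 17.7%, a difference of 8.10 percentage points at percentile 98.4. Neither share lay below the 95% range of its matched sets, and the share for ZFAT peaks with a B6 peak lay above it.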

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

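Of the tests below, those of the Lck-Cre depth and of a loss only at ZFAT sites, the pileup ratios for acetylation and for ZFAT, the draws in groups and the split of the B6 depth test by P score were chosen only after the result was seen. The test of a loss only at ZFAT sites replaced an earlier test whose value was bounded by the number of ZFAT-bound peaks, and its matched result was already known when it was chosen. A test of weak peaks was dropped because it restated its pattern. Control libraries were not part of the comparisons, but the background inferred at each peak holds their signal. The highest was 2038 scaled fragments, at the Lck-Cre H3K9ac/K27ac peak on chromosome 2, 98507255 to 98507448, where the ChIP pileup was 3130. Lck-Cre ZFAT, H3K9me3 and both B6 lists also had a peak at this position, with folds of 1.96, 2.92, 1.86 and 1.62.

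The Lck-Cre H3K9ac/K27ac list had 2225 peaks against 13016 in floxed thymocytes. Thinning the floxed pileups to the inferred Lck-Cre depth still left 12312 peaks above the threshold, and 9555 when fragments were drawn in groups of 10 to mimic duplicate reads, which argues against lower depth alone. A loss only at called ZFAT sites is also argued against, since 11049 of the 11416 floxed peaks not called in Lck-Cre had no ZFAT peak. With only 447 ZFAT-bound floxed peaks, this was fixed by the list sizes, and the matched test adds nothing to it. That test showed only that ZFAT-bound peaks were called in Lck-Cre about as often as others of like score. Their share was 17.9%, within the 15.0% to 21.3% of sets matched on score, against 12.1% of the other peaks. One fraction of enrichment, 0.174 at every site, gave the total and came within 9.75 percentage points of recurrence in each decile, but at recurring sites the ratio of Lck-Cre to floxed pileup, scaled to inferred depth, had a median of 0.484 where that fraction gave 0.288 to 0.297, a range of counting error only. The procedure that drew groups, run with single fragments, left 11972 peaks at the Lck-Cre depth. With its own fitted fraction it came within 6.28 points of recurrence and gave a ratio of 0.297 to 0.306. Fragments drawn in groups of 2 came within 5.28 points of recurrence but gave a ratio of 0.345 to 0.363. Groups of 5 and 10 gave 0.453 to 0.480 and 0.563 to 0.604 but missed recurrence by 22.2 and 25.9 points. No group size tried met both values. The thinning to 12312 peaks and the fit of 0.174 used the floxed control background scaled to depth, not the Lck-Cre control at each site. One common reduction therefore cannot be told apart from one that varied between sites. An origin in the ChIP, in the control or in the deletion stays open, because genotype and library coincide.

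The strongest ZFAT peaks were still called in Lck-Cre thymocytes. Of 25 such sites with a floxed pileup over 20 and no high background, 2 were at the ceiling in both lists and give no ratio; at the other 23 the Lck-Cre pileup, scaled to inferred depth, had a median of at most 0.355 of the floxed one, and 0.365 if those 2 are placed highest. At 5 high-background sites the ratio was 1.16, but control signal is part of the pileup there, so they give no measure of equal enrichment. The median of at most 0.355 argues against antibody binding without ZFAT at equal enrichment as the cause at all 25 sites. Only 18 of the 25 have a ratio known to be under 0.5. Of 91 floxed peaks below the ceiling with a P score of 20 or more, 8 were called in Lck-Cre, or 3 of 81 without high background, a restriction the prediction did not name; common fractions of 0.08 to 0.11 gave a count compatible with 8 and 0.04 to 0.08 with 3, while 0.355 and 0.150, medians at sites picked by being called, gave at least 14 on either set, so one remaining fraction cannot be told apart from unequal ones. Cells that kept ZFAT, and binding without ZFAT in a library of lower enrichment, remain open and untested.

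Most floxed ZFAT peaks had no B6 peak, and 1854 of the 2000 B6 peaks called against input had no floxed peak. Only the floxed peaks were tested against depth. Thinning the floxed pileups to the inferred B6 depth left 748 peaks above the threshold against 142 that recurred, and 590 with fragments drawn in groups of 10. At face value this argues against lower B6 depth alone over the whole list. However, the pileups are of peaks that passed the threshold on these same counts, which overstates how many should remain. The 748 also used the floxed control scaled to depth, not the B6 input. How far these points lower the excess was not tested. The excess lay in the weak peaks: 635 against 58 at P scores under 20, but 113 against 84 at 20 or more. The latter was within the limit of 1.5 times though above the interval of the recurring share. Draws in groups of 10 left 499 under 20, and 91.1 at 20 or more, which is within that interval. At 20 or more, lower depth therefore cannot be told apart from other causes. Weak peaks that do not recur and a difference between the mouse lines stay open and untested, since line and library coincide.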

How the results depend on the processing

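The 10 results were recomputed in 54 ways, 45 fixed before the data were examined and 9 added after seeing the data; 38 left a percent within its interval, a count within 1.5 times, or the ZFAT-bound difference within the range of matched sets. These include all 8 with an overlap of 50% of the shorter peak, all 8 within 500 bp, all 8 on autosomes, both at a false discovery rate of 1% and all 6 without regions of high control background. At that false discovery rate the floxed list kept 1719 ZFAT peaks and the Lck-Cre list 74, a ratio of 23.2 against 15.9 as reported. The H3K9ac/K27ac ratio stayed at 5.85. Every overlap stayed above chance, taken here from 100 circular shifts. At P scores of 10 or more in every list, ZFAT peaks numbered 681 floxed and 42 Lck-Cre, and H3K9ac/K27ac peaks 11458 and 1033. There, floxed ZFAT peaks were overlapped by Lck-Cre ZFAT in 4.26%, by B6 in 15.0% and by acetylation in 30.0%, H3K9me3 peaks by acetylation in 1.85%, and Lck-Cre acetylation peaks by floxed ones in 89.8%. The cause was not tested. With both lists at the length of the shorter, Lck-Cre overlap of floxed ZFAT was 27.8% and floxed overlap of Lck-Cre acetylation 41.5%, over lists restricted to their strongest peaks. B6 peaks called against IgG, a shorter list, overlapped 5.29% of floxed ZFAT peaks. ZFAT peaks with a B6 and no Lck-Cre peak were overlapped by acetylation in 61.9% and by H3K9me3 in 6.19%. Floxed ZFAT peaks with a P score of 20 or more, an added choice, had a B6 peak in 73.7% and acetylation in 59.6%. The difference between ZFAT-bound and other acetylation peaks turned from -0.10 to 5.63 percentage points without matching on score, in line with the higher scores of ZFAT-bound peaks, and to 8.10 for ZFAT-bound peaks with a B6 peak, whose cause was not tested. Matching on tag number and the promoter alternatives were not run. No paired analysis was possible because each ChIP group is 1 library, so the ChIP groups compared share only 1 replicate number. Many ZFAT peaks had small counts: 950 of 2000 B6 peaks called against input and 467 of 1719 floxed peaks rested on at most 5 inferred fragments.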

Other observations

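Strong ZFAT sites sometimes lay close together. On chromosome 2, floxed ZFAT peaks that were also called in Lck-Cre lay at 153458164 to 153458672 and at 153474730 to 153476162. Others lay on chromosome 11 at 84683044 to 84684591 and 84693207 to 84694031, and on chromosome 19 at 56622315 to 56622615 and 56622775 to 56623574. These regions were chosen after their values were seen.

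Peaks were unevenly spread over the chromosomes. Chromosome 11 held 10.5 floxed H3K9ac/K27ac peaks and 0.962 floxed ZFAT peaks per Mb, while chromosome X held 1.45 and 0.344. H3K9me3 peaks ran from 0.399 per Mb on chromosome X to 1.34 per Mb on chromosome 4. The B6 list called against input held 2 peaks on chromosome Y, with pileups of 6 and 5 fragments.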
